A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

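RNA sequencing was done on 15 samples of 5 yeast strains, 3 per strain, all in the S288C background. Per the labels' protocols, cells were grown at 30 °C in rich medium with 20 g/L glucose to an optical density of about 3, RNA was extracted from aliquots of 50 mL with a column kit, and libraries were sequenced on an Illumina instrument. HISAT2 is named, with no version, per the submitters' processing notes. The read counter, its strand setting and the genome build are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart with certainty, and reads of near-identical genes may have been split between copies or left out.

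The authors deposited 1 table with a raw read count and an FPKM value per gene and sample. The deposited counts are whole numbers that sum to a different total in each sample, and they were used as deposited. The deposited FPKM values were used only to check the table: each was reproduced from its count, the gene's length and 1 library total per sample, which lay 0.037% to 0.054% above the column's sum. The table holds 5980 nuclear protein-coding genes. Of these, 5977 have their identifier in the R64 reference annotation and 5972 the same start and end there, so coordinates are given in R64. Since 99.2% of the lengths are multiples of 3, they are coding lengths. The table used here has 0 mitochondrial genes, so the list of mitochondrially encoded respiratory genes was not analysed here, and neither were the carotenoid genes or the nuclease gene.

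Samples were grouped by the strain in their labels. The sum of counts per library was 16144808 to 21586409, so a gene with 0 reads is limited to 3 reads of that total. Folds against a strain whose libraries are all at 0 were computed against a floor of 3 counts over that strain's libraries and are given as "at least". These limits cover counting error only.

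Gene tests were run in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total 15) left 5814 genes, TMM factors scaled the libraries, and a robust quasi-likelihood model of all 15 samples with strain as the single factor was tested for 6 contrasts, with 1 joint test of the 4 β-carotene strains. Tests are two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes were called at an adjusted p below 0.05. Levels are TMM-normalised CPM, counts relative to library size. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic.

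Gene lists were tested with camera in limma 3.58.1 on log CPM values with a prior count of 2 and a preset correlation of 0.01, adjusted over 39 tested lists. These lists of pathways, regulons, cell type markers and the genes named by the labels were fixed before the data were examined, as were the tests of genes and lists, the naming rule and all alternatives except library totals alone and the libraries left out of the growth-state test; the tests of explanations chosen after the results were seen are named in the closing section. An estimated correlation and fry were the alternatives. Each of the 16 nuclear chromosomes was tested in the same way. The genes named are those of the label, mevalonate and ergosterol lists, the 6 with the largest rise and the 6 with the largest fall (4 and 4 between evolved strains) among called genes with a standard symbol, non-overlapping groups and at least 10 CPM in the higher group, and up to 4 members with the lowest adjusted p of each list called or with at least 50% of its members called one way; genes named in the closing section outside this rule were chosen after their values were seen.

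Alternatives were DESeq2 1.42.0, RLE scaling, library totals alone (chosen after seeing the data), no filter and a stricter filter (5 CPM in 3 samples), only the strains compared, a replicate block, limma-voom, an adjusted p below 0.01 and leaving out each library in turn. Whether the replicate numbers pair the libraries was checked from the correlation of deviations from the strain means, with the limit at 0.1 for every same-numbered pair of the strains compared. The labels name no shared batch or day, and the limit was passed in C0 against BY47419 alone: the 3 same-numbered pairs correlated at 0.116 to 0.321 and the 6 other pairs at -0.268 to 0.132. Blocked values, from the fit of all 15 samples, stand beside results of that comparison where they change a call or move a count by over 1.5 times. The gene test was tested on simulated counts for C0 against BY47419 over 5787 genes: it recovered 88.1% of genes changed 1.5-fold and 100% of those changed 2-fold and 4-fold, and 6 of its calls (3.03%) were false. These folds were given to 67, 67 and 66 genes, about as many up as down, with the dispersions of the fit. In the data 30.3% of genes were called in that comparison and 80.5% to 86.0% in the evolved strains against C0. The simulated rates therefore do not carry over to these comparisons. With 1 list shifted among 39, over 5814 genes, camera called that list and 0 others. Agreement between comparisons that share C0 was set against 20 simulations of unchanged groups.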

Results

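Transcript levels were measured by RNA sequencing in 5 strains of the budding yeast Saccharomyces cerevisiae, with 3 libraries per strain and 15 in all. BY47419 is the starting strain and carries the genome-editing nuclease spCas9-NG. C0 is the original β-carotene strain: in addition to the nuclease it expresses HMG1, the HMG-CoA reductase of the mevalonate pathway, and the carotenoid genes CrtE, CrtYB and CrtI. C3-06 and C5-63 are labelled as intermediate evolved strains and C7-143 as the final one. Per the labels' protocols, all cultures were grown in glucose-rich medium and harvested in exponential phase at an optical density of about 3. The growth phase of the single samples was not checked here. Ribosomal protein genes held 0.418% of the reads in BY47419, 0.482% in C0 and 5.41% in C7-143. Stress genes held 8.59%, 7.62% and 1.14%, so the same growth phase in all strains cannot be taken as given. The libraries held between 16144808 and 21586409 reads assigned to genes, with reads on 5839 to 5871 of the 5980 genes in each. Nothing in the labels says that the 3 libraries of a strain came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

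Ribosomal protein genes took a growing share of the reads and stress genes a shrinking one, in the order BY47419, C0, C3-06, C5-63 and C7-143. The ribosomal protein genes held 0.418% ± 0.0480 of the reads in BY47419 (SD, n = 3 here and below) and 0.482% ± 0.0236 in C0. Their share was 2.71% ± 0.433 in C3-06, 3.65% ± 0.243 in C5-63 and 5.41% ± 0.606 in C7-143. Genes of the general stress response driven by Msn2 and Msn4, together with trehalose and glycogen genes, held 8.59% ± 0.192 in BY47419, 7.62% ± 0.438 in C0 and 1.14% ± 0.126 in C7-143. Glycolysis genes held 3.49% ± 0.162 in C0 and 13% ± 1.0 in C7-143. In a principal component analysis of log values, the first component held 88.3% of the variance and placed all 6 libraries of BY47419 and C0 on one side and all 9 evolved libraries on the other. A pair of libraries stood apart within their strains: the chi-square per degree of freedom of the counts over genes was 103 and 74.2 for C3-06 replicate 1 against replicates 2 and 3, which were at 13.6 from each other, and 111 and 61.1 for BY47419 replicate 2 against replicates 1 and 3, at 15.1 from each other. C3-06 replicate 1 had 4.37% of its reads on stress genes, against 2.97% and 3.39% in the other two.

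**Figure D1:**
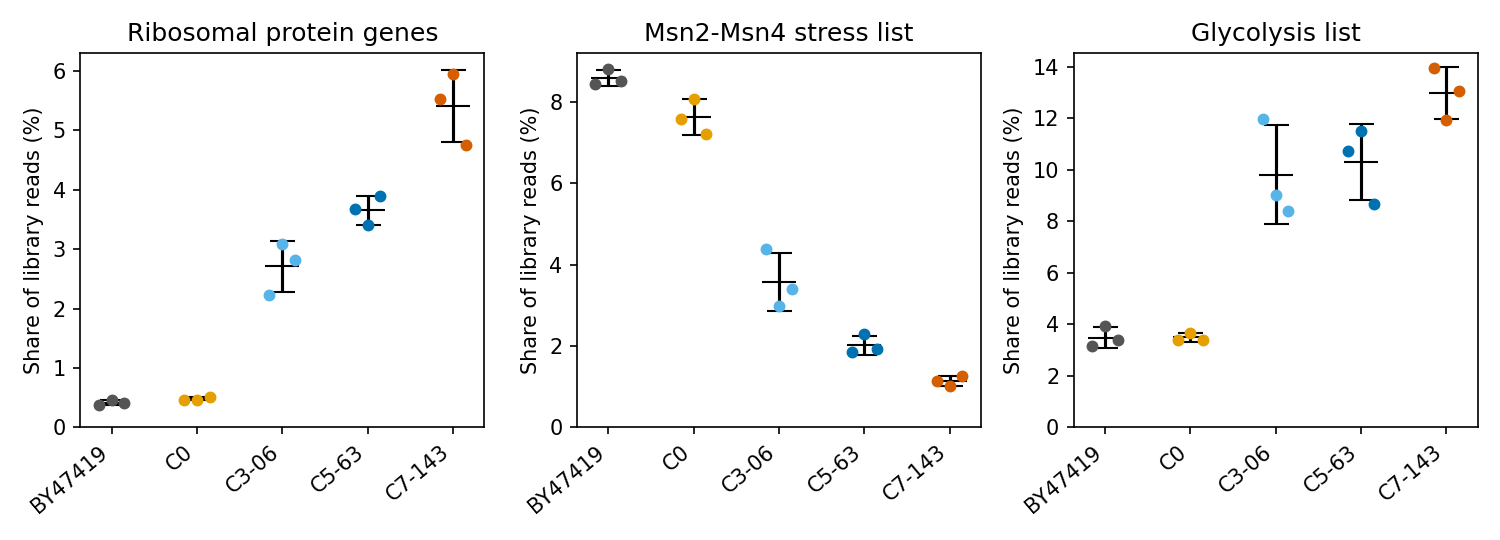
Share of each library's reads (%, y axis) on ribosomal protein genes, Msn2-Msn4 stress genes and glycolysis genes, by strain (x axis). Points are libraries, the horizontal mark is the mean and the bars the SD of 3 libraries; the ribosomal protein share lies below 0.51% in all 6 libraries of BY47419 and C0 and above 2.2% in all 9 evolved libraries.

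Genes named by the strain labels were examined first. HMG1 (YML075C, chromosome XIII, 115734 to 118898) stood at 79.8 ± 3.49 CPM (TMM-normalised counts relative to library size) in BY47419 and 2084 ± 95.2 CPM in C0, and at 999 ± 76.3, 519 ± 116 and 604 ± 74.9 CPM in C3-06, C5-63 and C7-143. Reads of the native and any introduced HMG1 copy are counted together. MET17 (the MET15 of the labels) and URA3, both given as deleted, had at most 1 read per strain in 52552428 to 61449674. LEU2 (YCL018W, chromosome III, 91324 to 92418), an enzyme of leucine synthesis that is also labelled as deleted, had 10346 reads in BY47419, 8491 in C0, 17634 in C5-63 and 14968 in C7-143. Reads of the native locus and of any introduced LEU2 copy are not told apart, so they do not check the label in those 4 strains. In C3-06 LEU2 had 0 reads in 60847082, and a count of 0 allows up to 3. HIS3 had 1608 to 8807 reads per strain, but the labelled allele removes only part of that gene, so these reads do not check the label. GAL80 (YML051W, chromosome XIII, 171594 to 172901), the repressor of the galactose genes and absent from the labels, had 7328 reads in BY47419 and 0 in every library of the other 4 strains. These limits cover counting error only.

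**Figure D2:**
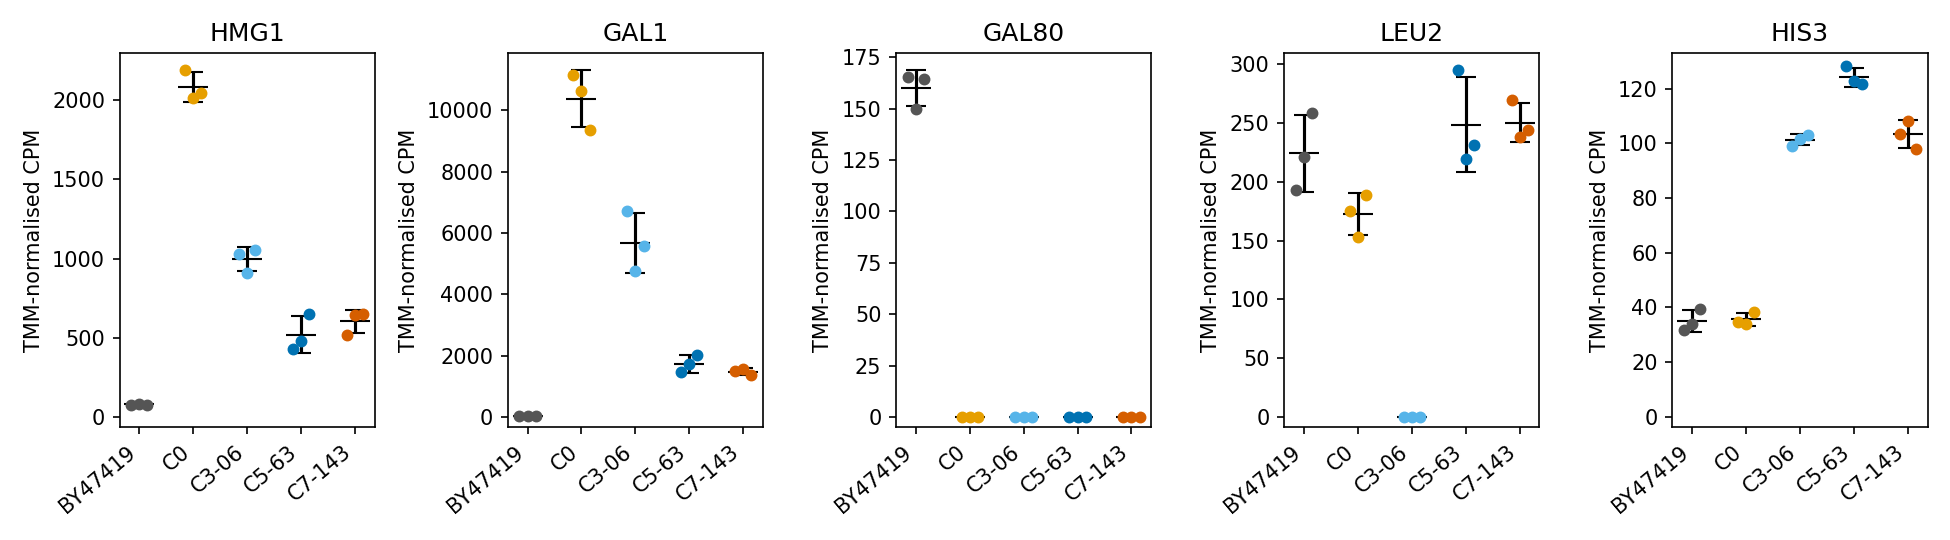
TMM-normalised CPM (y axis, linear) of HMG1, GAL1, GAL80, LEU2 and HIS3 in each strain (x axis). Points are libraries, the horizontal mark is the mean and the bars the SD of 3 libraries; GAL80 is at 0 in C0 and the evolved strains, and LEU2 is at 0 in C3-06.

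C0 was set against BY47419 to ask what differed in the original β-carotene strain. Galactose genes showed the largest rises. GAL1, the galactokinase (YBR020W, chromosome II, 279021 to 280607), rose from 26.1 ± 2.33 to 10375 ± 923 CPM, a log2 fold change of 8.64 ± 0.20 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.94e-14). GAL7, GAL10 and the galactose permease GAL2 rose by log2 9.09 ± 0.18, 8.90 ± 0.20 and 8.28 ± 0.23, and the inducer GAL3 by 3.36 ± 0.14. GAL80 was at least 2606-fold lower, with the floor set at 3 reads over the strain's libraries. HMG1 rose by log2 4.71 ± 0.15 (adjusted p = 2.30e-12). Genes for growth on carbon sources other than glucose fell: the log2 fold change was -3.78 ± 0.48 for malate synthase MLS1, -3.71 ± 0.44 for isocitrate lyase ICL1, -2.96 ± 0.43 for the acetate transporter ADY2, -2.77 ± 0.39 for the gluconeogenic FBP1 and -2.60 ± 0.34 for the lactate permease JEN1. Levels in BY47419 varied widely between libraries, with MLS1 at 2187 ± 1397 CPM (SD) and ICL1 at 3267 ± 1969. There ADY2 was at 403 ± 260 CPM, FBP1 at 518 ± 328 and JEN1 at 4232 ± 1976. Whether growth state contributed to these falls was not tested. ADY2 and FBP1 lost their calls when the fit held the BY47419 and C0 libraries alone (adjusted p = 0.0601 and 0.0565, edgeR). GAL1 and GAL3 are close relatives, so reads may be split between them.

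Among the lists fixed beforehand, 13 of 39 were called by camera in C0 against BY47419, 7 towards higher and 6 towards lower values, and each lost its call with an estimated correlation (adjusted p = 0.391 to 0.827). Counts adjusted over the list alone are given where they differ from those over all genes tested. In the galactose list 6 of 9 members rose and 1 fell; its median of 3.36 is the same with GAL80 at its bound. Ergosterol synthesis genes rose in 10 of 15 members (13 adjusted over the list alone), with a median log2 fold change of 0.46; ERG6, ERG1, ERG4 and ERG24 rose by 0.74 ± 0.12, 0.67 ± 0.14, 0.59 ± 0.10 and 0.46 ± 0.09 (adjusted p = 0.391 for the list with an estimated correlation). With the replicate block 11 of 15 rose, ERG7 passing at adjusted p = 0.0304 (edgeR). ERG7 also passed with DESeq2 (0.0465), library totals alone (0.0222), the stricter filter (0.0492), the BY47419 and C0 libraries alone (0.0485) and without BY47419 replicate 2 (0.0189). The count of 10 fell to 7 without BY47419 replicate 1 or 3 and to 9 without C0 replicate 1, 2 or 3. It was 12 with the stricter filter and with DESeq2, which also called 1 member lower. Library totals alone gave 13, as did leaving out BY47419 replicate 2. Of the 10 mevalonate genes 4 rose and 1 fell: besides HMG1 these were ERG10 (0.45), MVD1 (0.41) and ERG8 (0.35), and the isomerase IDI1 (-0.27). The list was at adjusted p = 0.391 by camera with an estimated correlation. Its mean log2 fold change was 0.60 and its median 0.19. HMG1 is part of this list in every comparison, and no list value without HMG1 is given here. MVD1 missed the threshold (edgeR adjusted p) at 0.122 without BY47419 replicate 1, 0.127 without BY47419 replicate 3, 0.0642 without C0 replicate 1, 0.0769 without C0 replicate 2 and 0.120 without C0 replicate 3, and IDI1 at 0.149 without BY47419 replicate 1, 0.158 without BY47419 replicate 3, 0.0771 without C0 replicate 1 and 0.145 without C0 replicate 2. MVD1 also missed it with limma-voom (adjusted p = 0.0878), and IDI1 with library totals alone (0.462) and with the BY47419 and C0 libraries alone (0.111). Gluconeogenesis and glyoxylate genes fell in 15 of 16 members (16 adjusted over the list alone) with a median of -1.69. Nuclear-encoded respiratory chain genes fell in 26 of 35 members (29 adjusted over the list alone), median -0.38, such as NDI1 (-0.67) and COX5A (-0.76). Genes of the tricarboxylic acid (TCA) cycle fell in 10 of 16 members, peroxisomal β-oxidation genes in 11 of 16 members (12 adjusted over the list alone) and acetyl-CoA supply genes in 5 of 9 members. The respiratory, TCA, β-oxidation and acetyl-CoA lists were at adjusted p = 0.391 with an estimated correlation, as was gluconeogenesis.

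Mating type a and pheromone genes rose in 10 of 17 members (11 adjusted over the list alone), with the protease gene BAR1 at 1.06 ± 0.20 and AGA1 at 0.92 ± 0.15, and 1 fell adjusted over the list alone. Methionine and sulfur genes rose in 11 of 25 members (12 adjusted over the list alone), with 1 the other way (2 adjusted over the list alone); SAM1 and SAM2, the S-adenosylmethionine synthetases, rose by 1.42 and 0.76, though reads of these near-identical genes may be split between them. Both lists were at adjusted p = 0.391 with an estimated correlation. The PAU family, whose near-identical members share reads, rose in 5 of 16 (adjusted p = 0.391 with an estimated correlation). With the replicate block 3 of them passed, PAU2 ending at adjusted p = 0.0593 (edgeR), and leaving out 1 library left 3 without BY47419 replicate 1 or 2 and 2 without BY47419 replicate 3 or any C0 replicate. Ribosomal protein genes were called as a list at a median of 0.10, yet only 10 of 138 rose over all genes and 0 adjusted over the list alone (adjusted p = 0.827 with an estimated correlation); this call was lost at adjusted p = 0.0521 without BY47419 replicate 1. The count of 10 was 3 without BY47419 replicate 1, BY47419 replicate 3 or C0 replicate 2 and 1 without C0 replicate 3, and the 11 methionine and sulfur genes were 7 without BY47419 replicate 1 and 6 without BY47419 replicate 3. Oxidative stress genes were called lower at adjusted p = 0.0486, with 7 of 25 falling and 1 rising; the catalase CTT1 fell by 0.97. That list's median of -0.14 turns to 0.0060 when library totals alone set the scale, and its adjusted p was 0.538 with an estimated correlation. It was also 0.0794 without BY47419 replicate 2, 0.0719 without C0 replicate 1 and 0.0896 without C0 replicate 3, and the replicate block ended the call at 0.0666, with 2 rising.

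In total 712 genes were higher and 1049 lower in C0 than in BY47419 among 5814 tested, of which 46 and 47 changed at least 2-fold. The libraries of the strains did not overlap for 40.9% of genes, against 10% by chance if all libraries are exchangeable. That 10% takes no account of pairing by replicate number. The split depends on the scaling: with library totals alone, an alternative chosen after seeing the data that moved the median gene to 0.13, 1279 genes were higher and 318 lower. That scaling left 16 respiratory chain, 6 TCA cycle, 6 β-oxidation and 4 oxidative stress genes lower and 24 ribosomal protein genes higher. The counts also rest on single libraries: they were 377 and 568 without BY47419 replicate 1, 389 and 625 without BY47419 replicate 3, and 392 and 635 without C0 replicate 2.

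C3-06 was compared with C0 to ask what differed in this intermediate strain. Genes for ribosomal proteins rose and genes for respiration, stress and alternative carbon sources fell. RPS22A, a ribosomal protein of the small subunit, went from 5.0 ± 1.24 to 165 ± 39.8 CPM, a log2 fold change of 5.05 ± 0.21 (adjusted p = 8.28e-12, edgeR with Benjamini-Hochberg adjustment). The G1 cyclin PCL1 rose by 4.83 ± 0.44, the cell wall protein NCW2 by 4.55 ± 0.19 and the thymidylate synthase CDC21 by 4.14 ± 0.16. LEU2 was at least 3766-fold lower. The next largest falls were RGI2 (-5.04 ± 0.34), the gluconeogenic PCK1 (-4.86 ± 0.32), SPG1 (-4.84 ± 0.25), the high-affinity glucose transporter HXT6 (-4.71 ± 0.25) and the chaperone SSA3 (-4.47 ± 0.12). RPS22A and HXT6 have near-identical partners (RPS22B and HXT7), as do many ribosomal protein genes, so the level of a single copy is uncertain.

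Camera called 16 of 39 lists in C3-06 against C0, 7 higher and 9 lower, all at adjusted p = 0.50 with an estimated correlation, where none was called. Ribosomal protein genes rose in 137 of 138 members (138 adjusted over the list alone), with a median log2 fold change of 2.50, and ribosome biogenesis genes in 36 of 38 members, with 2 the other way, median 1.12, with NOP1 at 3.19. Ergosterol genes rose in 14 of 15 members, median 1.91; ERG2 rose by 2.80 ± 0.13, ERG4 by 2.41 ± 0.10 and the squalene epoxidase ERG1 by 2.40 ± 0.15, whereas the squalene synthase ERG9 was at -0.08 ± 0.06 and did not pass, except by DESeq2 (adjusted p = 0.0467). Glycolysis genes rose in 17 of 20 members, with 1 the other way, TDH2 at 3.34 and PGI1 at 2.27. Fatty acid synthesis genes rose in 9 of 11 members, with 2 the other way, with the elongase ELO2 at 3.55, cell wall genes in 18 of 23 members, with 2 the other way and Gcn4-controlled amino acid genes in 30 of 43 members, with 11 the other way. These 7 lists were all at adjusted p = 0.50 with an estimated correlation. Respiratory chain genes fell in 35 of 35 members, median -1.15, and TCA cycle genes in 14 of 16 members, with 1 the other way. Gluconeogenesis and glyoxylate genes fell in 16 of 16 members, median -2.65, β-oxidation genes in 14 of 16 members, with 1 the other way, heat shock genes in 15 of 21 members, with 1 the other way and Msn2-Msn4 stress genes in 19 of 23 members, median -1.38. Iron genes fell in 18 of 26 members, with 3 the other way and methionine and sulfur genes in 18 of 25 members (19 adjusted over the list alone), with 6 the other way. Galactose genes fell in 8 of 9 members, with a median of -1.0 over the 8 members other than GAL80; GAL3 fell by 1.81 and GAL7 by 1.14. The 9 lower lists stood at adjusted p = 0.50 with an estimated correlation too.

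HMG1 fell by 1.06 on the log2 scale in C3-06 (SE 0.13, adjusted p = 1.49e-06, edgeR). Of the other mevalonate genes ERG10 (1.63), ERG20 (1.55), ERG13 (1.31), MVD1 (1.20), BTS1 (0.91) and ERG12 (0.78) rose, 6 of 10 members, while HMG2, ERG8 and IDI1 did not pass. HMG2 passed as lower without C0 replicate 3 (-0.23, adjusted p = 0.0332, edgeR) and without C3-06 replicate 1 (-0.25, 0.0101), and ERG8 as higher with library totals alone (0.17, 0.0488). The list, HMG1 included, was not called by camera (adjusted p = 0.159, and 0.50 with an estimated correlation). Over all genes 2387 were higher and 2292 lower in C3-06, 977 and 652 of them at least 2-fold, and the libraries did not overlap for 81.4% of genes. With library totals alone, chosen after seeing the data, the median gene moved to 0.22 and the split to 2820 higher and 1702 lower.

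In C5-63, the other intermediate strain, ribosomal protein and cell wall genes were above C0 and genes for stress, respiration and alternative carbon sources below it. The purine synthesis gene IMD2 rose from 34.8 ± 1.95 to 899 ± 156 CPM, a log2 fold change of 4.69 ± 0.13 (adjusted p = 2.15e-13, edgeR), and the cell wall glucanase-like gene SCW10 rose by 4.69 ± 0.19. RPS22A, PCL1, CDC21 and RPL17B rose by 5.92, 5.79, 4.72 and 4.71. The largest falls were RGI2 (-7.07 ± 0.41), HXT6 (-6.52 ± 0.27), PCK1 (-5.88 ± 0.33), SPG1 (-5.53 ± 0.26), the cytochrome oxidase subunit COX26 (-5.37 ± 0.24) and SIP18 (-5.37 ± 0.28). LEU2, at 0 in C3-06, was 0.53 ± 0.12 above C0 here.

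Camera called in C5-63 the 16 lists called in C3-06, 7 higher and 9 lower, and none with an estimated correlation (adjusted p = 0.501 to 0.516). Ribosomal protein genes rose in 137 of 138 members, median 2.86, ribosome biogenesis genes in 30 of 38 members, with 2 the other way, ergosterol genes in 13 of 15 members, median 2.12, and fatty acid synthesis genes in 9 of 11 members, with 2 the other way. Glycolysis genes rose in 17 of 20 members, with 3 the other way, cell wall genes in 15 of 23 members, with 4 the other way and Gcn4-controlled genes in 30 of 43 members, with 8 the other way. Respiratory chain genes fell in 35 of 35 members, median -1.90, stress genes in 22 of 23 members, median -2.36, and heat shock genes in 20 of 21 members. TCA cycle genes fell in 15 of 16 members, gluconeogenesis genes in 16 of 16 members, β-oxidation genes in 14 of 16 members, with 1 the other way, iron genes in 19 of 26 members, with 3 the other way and sulfur genes in 18 of 25 members (19 adjusted over the list alone), with 5 the other way. All of these were at adjusted p = 0.501 to 0.516 with an estimated correlation. Galactose genes fell in 8 of 9, median -2.43 without GAL80 (adjusted p = 0.501 with an estimated correlation), and HMG1 fell by 2.01 (SE 0.13). Of the other mevalonate genes 6 rose, HMG2 fell (-0.25 ± 0.08, adjusted p = 0.0136, edgeR), and ERG8 and IDI1 did not pass. The list, HMG1 included, was not called by camera (adjusted p = 0.133, and 0.516 with an estimated correlation). HMG2 lost its call without C0 replicate 2 (adjusted p = 0.0928, edgeR) and without C5-63 replicate 3 (0.0828). With library totals alone HMG2 was at 0.059 and did not pass, and ERG8 (0.30, adjusted p = 0.00163, edgeR) and IDI1 (0.26, 0.0300) passed as higher. In all, 2405 genes were higher and 2428 lower, 1126 and 903 at least 2-fold, with non-overlapping libraries for 85.2%. Library totals alone, chosen after seeing the data, moved the median gene to 0.30 and the split to 3035 higher and 1684 lower.

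C7-143, the final strain, differed most from C0 in number of genes. RPS22A rose from 5.0 ± 1.24 to 429.6 ± 55.2 CPM, a log2 fold change of 6.43 ± 0.21 (adjusted p = 1.95e-13, edgeR quasi-likelihood test). PCL1 rose by 6.21 ± 0.43, the mannoprotein gene TIR3 by 5.62 ± 0.27 and CDC21 by 5.46 ± 0.16; the ribosomal protein genes RPS9B and RPL17B, which have near-identical partners, rose by 5.72 ± 0.24 and 5.51 ± 0.13. SPG4 fell from 2434 ± 144 to 12.6 ± 5.43 CPM, a log2 fold change of -7.59 ± 0.32 (adjusted p = 3.65e-12, edgeR). RGI2, the membrane stress protein HSP30, HXT6, SPG1 and DDR2 changed by -7.50 ± 0.43, -6.88 ± 0.34, -6.78 ± 0.28, -6.78 ± 0.28 and -6.73 ± 0.27.

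Counts adjusted over the list alone were the same as those over all genes in the lists named here. Of 39 lists, camera called 9 higher and 10 lower in C7-143 than in C0, and 0 with an estimated correlation (adjusted p = 0.469 to 0.497). Ribosomal protein genes rose in 138 of 138 members, median 3.64, and ribosome biogenesis genes in 36 of 38 members, with 2 the other way, median 1.76, with NOP1 and GAR1 at 4.26 ± 0.19 and 3.80 ± 0.14. Glycolysis genes rose in 17 of 20 members, with 3 the other way, with TDH2 at 4.75 ± 0.21 and ENO2 at 4.83 ± 0.22, 2 genes with near-identical partners; the minor pyruvate decarboxylase PDC6 was among the 3 that fell (-2.39). Fatty acid synthesis genes rose in 9 of 11 members, with 2 the other way, median 2.70, led by ELO2 (5.09 ± 0.16) and ELO3 (4.69 ± 0.19). Gcn4-controlled amino acid genes rose in 31 of 43 members, with 8 the other way, cell wall genes in 16 of 23 members, with 6 the other way, unfolded protein response genes in 11 of 14 members, with 3 the other way and proteasome genes in 24 of 32 members, with 4 the other way, although RPN4, the activator of proteasome genes, fell (-2.36). All of these were at adjusted p = 0.469 to 0.497 with an estimated correlation.

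Respiratory chain genes fell in 35 of 35 members in C7-143, median -2.04, with QCR7 at -2.89 ± 0.11 and RIP1 at -2.73 ± 0.10. TCA cycle genes fell in 14 of 16 members, median -1.93, with SDH1 at -3.09 ± 0.12. Stress genes fell in 23 of 23 members, median -3.50, with HSP12 at -5.94 ± 0.23, and heat shock genes in 17 of 21 members, with 1 the other way, median -2.13. Gluconeogenesis genes fell in 16 of 16 members, median -3.85, β-oxidation genes in 14 of 16 members, with 1 the other way, iron genes in 22 of 26 members, with 2 the other way with SIT1 at -4.23, oxidative stress genes in 16 of 25 members, with 6 the other way and nitrogen-catabolite-repressed genes in 16 of 23 members, with 4 the other way. Galactose genes fell in 8 of 9, median -2.79 without GAL80; GAL1 still stood at 1484 ± 101 CPM, against 26.1 ± 2.33 in BY47419. The 10 lower lists were at adjusted p = 0.469 to 0.497 with an estimated correlation.

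Ergosterol synthesis genes rose in C7-143 against C0. The C-4 methyl sterol oxidase ERG25 (YGR060W, chromosome VII, 610564 to 611493) rose from 72.4 ± 5.61 CPM in C0 to 1532 ± 197, a log2 fold change of 4.40 ± 0.19 (adjusted p = 2.37e-12, edgeR). ERG2, ERG11 (lanosterol demethylase), ERG6 and ERG4 rose by 3.81 ± 0.13, 3.63 ± 0.17, 3.36 ± 0.13 and 3.14 ± 0.10. In total 14 of 15 members of the ergosterol list rose, at a median of 2.74 (camera adjusted p = 1.15e-04, and adjusted p = 0.469 with an estimated correlation), and the exception ERG7 was at 0.10 ± 0.07 (0.24 with library totals alone, where it passed at edgeR adjusted p = 0.0320). The regulator UPC2 rose by 2.71. In the mevalonate list 7 of 10 rose, among them the farnesyl diphosphate synthase ERG20 (2.39), ERG13 (2.08) and ERG10 (1.94). HMG1 fell by 1.79 (SE 0.13), and the list missed its threshold by camera (adjusted p = 0.0542, and adjusted p = 0.469 with an estimated correlation), although it passed at 0.0457 without C0 replicate 2 and 0.0473 without C7-143 replicate 3. These list values include HMG1, whose reads count any introduced copy. ERG8 and HMG2 did not pass, but ERG8 passed as lower without C0 replicate 3 (-0.19, adjusted p = 0.0219, edgeR) and HMG2 as higher with library totals alone (0.24, 0.00310).

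**Figure D3:**
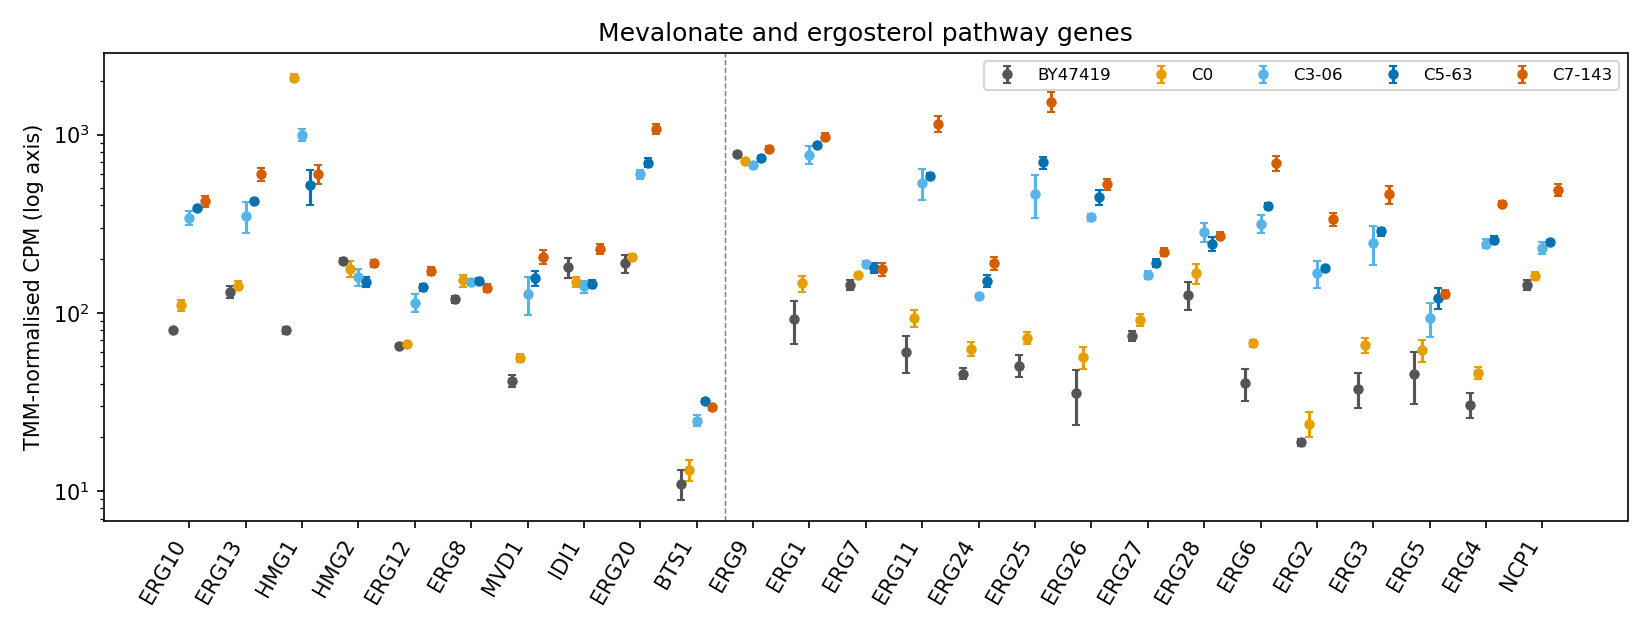
TMM-normalised CPM (y axis, log scale) of mevalonate genes (left of the dashed line) and ergosterol genes (right) in the 5 strains (colours). Points are means and bars the SD of 3 libraries; ERG25 lies at 72.4 in C0 and 1532 in C7-143, and HMG1 at 2084 and 604.

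In all 2481 genes were higher and 2518 lower in C7-143 than in C0, with 1388 and 1152 changed at least 2-fold and non-overlapping libraries for 87.3% of genes. With library totals alone, chosen after seeing the data, the median gene moved to 0.12 and the counts to 2684 higher and 2177 lower.

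**Figure D4:**
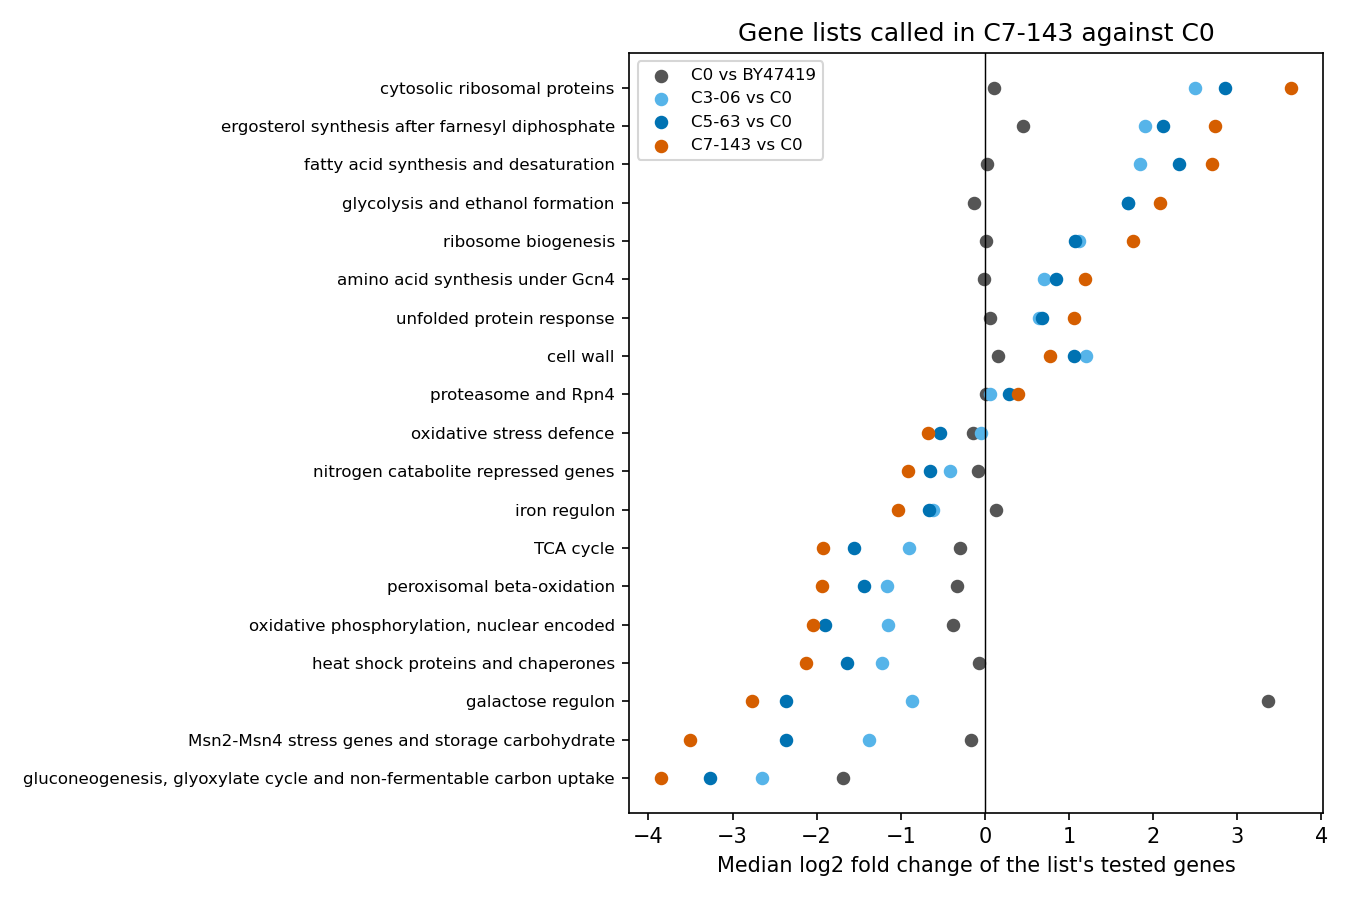
Median log2 fold change (x axis) of the tested genes in each list called in C7-143 against C0 (y axis), for C0 against BY47419 and each evolved strain against C0 (colours). Each point is the median of 1 list; ribosomal protein genes lie at 0.10, 2.50, 2.86 and 3.64, and stress genes at -0.16, -1.38, -2.36 and -3.50. The galactose medians include GAL80, which has 0 reads in all strains but BY47419. With library totals alone, the C0 against BY47419 medians of glycolysis, heat shock, oxidative stress, Gcn4 and nitrogen genes and the C3-06 median of oxidative stress genes change sign.

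The changes of the evolved strains against C0 were then set against each other. Genes higher in all 3 evolved strains numbered 2036 and genes lower in all 3 numbered 2002. Some were called in opposite directions, with the difference between the strains called as well: 57 genes were higher in C3-06 and lower in C7-143, and 60 lower in C3-06 and higher in C7-143 (101 and 27 with library totals alone). For C3-06 and C5-63 these counts were 21 and 16, and for C5-63 and C7-143 16 and 23 (61 and 6 with library totals alone). The counts for C3-06 and C5-63 were 15 and 7 without C0 replicate 1, 12 and 8 without C0 replicate 3 and 17 and 10 without C3-06 replicate 1, and those for C5-63 and C7-143 were 12 and 15 without C0 replicate 1, 11 and 12 without C0 replicate 3 and 13 and 13 without C7-143 replicate 1. C3-06 and C7-143 shared 2106 higher genes, where independent lists of those sizes would share 1019, and 2064 lower genes against 993. C5-63 shared 2156 higher and 2092 lower genes with C3-06, against 987 and 957, and 2220 and 2266 with C7-143, against 1026 and 1052. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.946 for C3-06 with C5-63, 0.921 for C3-06 with C7-143 and 0.976 for C5-63 with C7-143. Their covariances were 1.34, 1.57 and 1.96, and 91.2%, 87.7% and 92.2% of genes had the same sign. All 3 comparisons use the same C0 libraries: in 20 simulations of unchanged groups the mean r was 0.526, 0.512 and 0.513, the covariance 0.0092, 0.0090 and 0.0090, and 67.3%, 67.0% and 67.2% of genes shared their sign, with 0 shared calls. The covariances less their simulated values were 1.33, 1.56 and 1.95. The 3 C0 libraries do not make parts of at least 2 each, so the comparison with separate controls was not run, and part of the excess in r, in shared signs and in shared calls may come from the shared controls.

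Between the intermediate strains, C5-63 stood below C3-06 for stress, respiratory and galactose genes. LEU2 was at least 5410-fold higher in C5-63. The cell wall gene PIR3 fell from 940.1 ± 250.3 to 94.0 ± 21.4 CPM, a log2 fold change of -3.32 ± 0.25 (adjusted p = 1.62e-06, edgeR), the glucose transporter HXT4 fell by 2.41 (SE 0.23), DDR2 by 2.39 (SE 0.22) and the small heat shock gene HSP26 by 2.29 (SE 0.29). TIR3, the cell wall sensor gene WSC4 and UTR2 rose by 1.93 ± 0.21, 1.76 ± 0.17 and 1.72 ± 0.22. HMG1 fell by 0.95 (SE 0.13), from 999 ± 76.3 to 519 ± 116 CPM. Of the ergosterol genes 4 of 15 rose, with ERG25 at 0.58. The count was 2 without C3-06 replicate 1, where ERG27 and ERG6 lost their calls (adjusted p = 0.0722 and 0.135, edgeR), and 2 without C5-63 replicate 2, where ERG27 and ERG24 did (0.0709 and 0.0581), and 6 with DESeq2 and with library totals alone. The list was not called (adjusted p = 0.0598, and 0.573 with an estimated correlation) but passed at 0.0385 without C3-06 replicate 2 and 0.0325 without C3-06 replicate 3. Of the mevalonate genes BTS1 (0.36) and ERG12 (0.29) rose, 2 of 10 (5 adjusted over the list alone), and HMG1 fell; the list was not called (adjusted p = 0.257, and 0.573 with an estimated correlation). With DESeq2, RLE scaling or library totals alone 5 rose, without C3-06 replicate 2 or 3 there were 4, and without C3-06 replicate 1 there was 1.

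Camera called 6 lists higher and 9 lower between these strains, and none with an estimated correlation (adjusted p = 0.436 to 0.573). Respiratory chain genes fell in 34 of 35 members, median -0.73, TCA cycle genes in 12 of 16 members (13 adjusted over the list alone), stress genes in 21 of 23 members, median -0.86, heat shock genes in 16 of 21 members (18 adjusted over the list alone) and hexose transporter genes in 8 of 15 members, with 2 the other way. Galactose genes fell in 8 of 9, median -0.86 without GAL80, with GAL1 at -1.71. Gluconeogenesis genes fell in 8 of 16 members, oxidative stress genes in 12 of 25 members, with 2 the other way and iron genes in 9 of 26 members (10 adjusted over the list alone), with 3 the other way; the iron list lost its call at adjusted p = 0.0892 without C3-06 replicate 2, 0.0602 without C5-63 replicate 2 and 0.0596 without C5-63 replicate 3. Ribosomal protein genes rose in 83 of 138 members (91 adjusted over the list alone), with 2 the other way, median 0.35, proteasome genes in 25 of 32 members (26 adjusted over the list alone), Gcn4-controlled genes in 18 of 43 members, with 6 the other way, fatty acid synthesis genes in 6 of 11 members, phospholipid genes in 9 of 16 members, with 1 the other way and mating type a genes in 8 of 17 members, with 1 the other way. For all of these the adjusted p with an estimated correlation was 0.436 to 0.573. Without C3-06 replicate 1 the counts were 55 for ribosomal protein genes, 13 for stress genes and 4 for gluconeogenesis genes, without C5-63 replicate 1 there were 7 oxidative stress genes, and with library totals alone 3 iron genes. Over all genes 1151 were higher and 1221 lower, and 35 and 106 changed at least 2-fold; the latter count was 67 without C3-06 replicate 1. Libraries did not overlap for 57.1% of genes, and library totals alone, chosen after seeing the data, gave 1546 higher and 761 lower with the median gene at 0.098.

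C7-143 was above C5-63 for ribosomal protein, sterol, fatty acid synthesis and phospholipid genes. RPL9A and RPL2A, both with near-identical partners, rose by 1.92 ± 0.16 and 1.66 ± 0.13, TIR1 by 1.77 ± 0.19 and the adenosine kinase ADO1 by 1.61 ± 0.07, from 279.8 ± 2.07 to 853 ± 28.0 CPM (adjusted p = 4.07e-10, edgeR). SPG4, HSP26, YRO2 and HSP30 changed by -2.26 ± 0.27, -2.13 ± 0.29, -1.88 ± 0.22 and -1.88 ± 0.27. ERG25 rose by 1.13 ± 0.16, NCP1 by 0.98 ± 0.08, ERG11 by 0.97 ± 0.15 and IDI1 by 0.65 ± 0.09. HMG1 stood at 0.22 ± 0.13 (adjusted p = 0.176, edgeR) and did not pass; without C5-63 replicate 3 it was at 0.40 and passed (adjusted p = 0.00813, edgeR).

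Camera called 10 lists higher and 11 lower in C7-143 than in C5-63, and 0 with an estimated correlation (adjusted p = 0.498 to 0.635). Ribosomal protein genes rose in 122 of 138 members (124 adjusted over the list alone), with 3 the other way, median 0.69, ribosome biogenesis genes in 33 of 38 members (35 adjusted over the list alone), ergosterol genes in 10 of 15 members, median 0.33, and mevalonate genes in 6 of 10 members, median 0.33. With library totals alone both sterol list medians were 0.16, 7 of 15 ergosterol genes and 3 of 10 mevalonate genes were higher, and ERG8 was lower (-0.29, adjusted p = 0.00415, edgeR), as ERG13 (adjusted p = 0.0589), ERG12 (0.253) and MVD1 (0.262) lost their calls. The 6 mevalonate genes were 5 without C5-63 replicate 1 or 2 or C7-143 replicate 1 or 2, and 7 without C5-63 replicate 3. Fatty acid synthesis genes rose in 8 of 11 members, with 1 the other way, with the acetyl-CoA carboxylase ACC1 at 1.29, phospholipid genes in 10 of 16 members, with 2 the other way, with ITR1 at 1.31 and CHO2 at 1.18, Gcn4-controlled genes in 22 of 43 members (23 adjusted over the list alone), with 5 the other way, glycolysis genes in 10 of 20 members (11 adjusted over the list alone), with 2 the other way and unfolded protein response genes in 7 of 14 members, with 1 the other way. Proteasome genes rose in 12 of 32 members, with 1 the other way, but that list's median of 0.11 turns to -0.052 with library totals alone. Stress genes fell in 17 of 23 members (20 adjusted over the list alone), respiratory chain genes in 21 of 35 members (22 adjusted over the list alone), with 1 the other way, TCA cycle genes in 9 of 16 members, with 1 the other way, β-oxidation genes in 10 of 16 members, iron genes in 13 of 26 members and nitrogen-catabolite-repressed genes in 11 of 23 members. Hexose transporter genes fell in 6 of 15 members, oxidative stress genes in 10 of 25 members, with 1 the other way, gluconeogenesis genes in 5 of 16 members (4 adjusted over the list alone), meiosis genes in 6 of 15 members and galactose genes in 4 of 9 members, median -0.30 without GAL80. For all of these the adjusted p with an estimated correlation was 0.498 to 0.635. The calls of some lists rested on single libraries: the adjusted p was 0.126 without C5-63 replicate 3, 0.0692 without C7-143 replicate 1 and 0.0606 without C7-143 replicate 3 for glycolysis, 0.0637 without C5-63 replicate 2, 0.0741 without C5-63 replicate 3, 0.0568 without C7-143 replicate 1 and 0.0549 without C7-143 replicate 3 for galactose genes, and 0.0502 without C5-63 replicate 2, 0.0921 without C5-63 replicate 3, 0.0715 without C7-143 replicate 1 and 0.0604 without C7-143 replicate 2 for hexose transporters. The 6 hexose transporter genes were 3 without C7-143 replicate 1 and 2 without C7-143 replicate 2, and the 33 ribosome biogenesis genes were 21 without C7-143 replicate 2. With library totals alone the counts higher were 12 for ribosome biogenesis, 9 for Gcn4, 5 for fatty acid and 5 for proteasome genes, and those lower were 17 for oxidative stress, 17 for nitrogen, 14 for TCA cycle and 7 for galactose genes. In total 1451 genes were higher and 1387 lower, with non-overlapping libraries for 62.0%; 112 and 57 changed at least 2-fold, the latter count being 37 without C5-63 replicate 2 and 35 without C7-143 replicate 2. Library totals alone, chosen after seeing the data, moved the median gene to -0.18 and turned the split to 714 higher and 2314 lower.

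The strains were put in the order C0, C3-06, C5-63 and C7-143, but whether each descends from the one before was not tested. Genes called higher at every step numbered 428, and 409 were lower at every step (285 and 356 with library totals alone). Without C5-63 replicate 1 these counts were 317 and 305. A joint test of the 4 β-carotene strains found 5408 of 5814 genes that differed among them. Of the 4 tested genes expressed in cells of mating type α, 4, 4 and 3 were higher than in C0 in C3-06, C5-63 and C7-143 (4, 4 and 2 adjusted over the list alone), with STE3 at 222 to 562 reads per evolved library, and MATALPHA1 had 0 reads in every library. The call of STE3 in C7-143 was lost with limma-voom (adjusted p = 0.0573) and, by edgeR, without C0 replicate 1 (0.0674), C0 replicate 3 (0.205), C7-143 replicate 1 (0.102) and C7-143 replicate 2 (0.165). This list was not called by camera against C0 (adjusted p = 0.128, 0.218 and 0.604, and 0.50, 0.501 and 0.634 with an estimated correlation). Of the chromosomes camera called 0 of 16 in each of the 6 comparisons, 0 at an unadjusted p below 0.05 and 0 with an estimated correlation, and the chromosome medians lay between -0.13 and 0.068. Arm medians, which were not tested, lay between -0.24 and 0.37, the ends being in comparisons with C0. They were 0.37 in C3-06 and 0.33 in C5-63 against C0 for the right arm of chromosome XIV (76 genes), -0.22 in C5-63 and -0.23 in C7-143 for the left arm of XII (58 genes), and in C7-143 against C0 -0.24 for the right arm of XI (101 genes) and 0.23 for the left arm of IV (230 genes).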

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

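The tests on LEU2's nearest genes with reads, on depth, both swaps, scaling, galactose in the medium, the GAL80 segment and GAL80 function, the libraries left out of the growth-state test, and all counts over other splits of the samples, were chosen only after the result was seen; those on coding length, growth state with all libraries and the segment beside LEU2 were written before.

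Of the genes named in the comparisons of evolved strains with C0, LEU2 was the one called in opposite directions in a pair of them. It was at 0 reads in C3-06 and above C0 in both others: at least 5410-fold higher in C5-63 than in C3-06 and at least 5459-fold higher in C7-143 (adjusted p = 4.98e-12 and 4.93e-12, edgeR). Depth argues against chance absence, since 11299 reads would be expected at the C0 level, and an exchange of all 3 C3-06 libraries with those of BY47419 is argued against by HMG1, at least 10.9-fold higher in each of them than in any BY47419 library, but an exchange with those of C0, C5-63 or C7-143 stays open, because the 2565 or more LEU2 reads in every library of these would then be the same. Loss of the adjacent segment cannot be judged from both neighbours, because YCL020W has 0 reads in all 5 strains, while NFS1 on the other side has 9354 reads in C3-06; a loss reaching the nearest genes with reads is argued against by 543 reads of YCL021W-A. A LEU2 copy carried by the other strains and lost or replaced in C3-06 may account for the pattern, and stays open as untested, as does an outside sample under that label.

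GAL80 had 0 reads in C0, where the galactose genes were high. Galactose in the medium alone would leave GAL80 transcribed, so its 0 reads argue against that as the whole explanation, and loss of the segment around it is argued against by 2040 reads of AIM32 and 43452 of its other neighbour SUR7. GAL80 transcript was thus not detected in C0. Loss of GAL80 function as the cause of the high galactose genes stays open: the rise of 6 of 6 Gal4 targets restates the pattern and does not test it. Whether the gene was removed on purpose is not given in the labels. The later fall of galactose genes in the evolved strains, with GAL80 still at 0, has no tested explanation here.

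Ribosomal protein genes rose and stress and respiration genes fell from C0 to C7-143. Coding-length bias is argued against by a median log2 fold change of -0.061 in 353 genes of matched length, against 3.64 for ribosomal protein genes. With library totals alone the ribosomal protein median was 3.78. The TMM factors, at a mean of 0.934 in C0 and 1.03 in C7-143, allow only a small move, so that check could hardly have failed. A scale factor moves all genes of a library alike, so the gap between ribosomal protein and matched genes argues against scaling by a few abundant genes as its source. Libraries lying at different points of 1 growth-state axis could not be judged. The main axis of variation within strains, with 25.4% of that variance, correlated with C7-143 minus C0 at an absolute r of 0.647 across genes. That value passed the limit written beforehand for this explanation. A rule that it also hold without each library was added after the result was seen. The r was 0.379 without C3-06 replicate 1 and 0.429 without C3-06 replicate 2. It was 0.0998 without BY47419 replicate 2 and C3-06 replicate 1, which lay farthest out on that axis. Because that pair was picked for its place on the axis, a fall was likely in advance and does not weigh against the explanation. A growth state caused by the strain's genotype would give the same values, and so would a difference in harvest point, which the labels give as 1 density for all. These stay open.

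In each of the 6 comparisons only 10 splits of the libraries exist, too few for a share under 0.05; 1 split, the real one, gave as many genes. The real counts were 1761, 4679, 4833, 4999, 2372 and 2838 for C0 against BY47419, the 3 evolved strains against C0, C5-63 against C3-06 and C7-143 against C5-63, and the highest of the other splits gave 16, 0, 0, 0, 0 and 0. In C0 against BY47419, where the replicate numbers passed the limit for pairing, the 3 other splits that part all 3 pairs gave 0 genes, and the 6 that part 1 pair gave 0 to 16. For the joint test of the β-carotene strains, 1 of 100 splits, the real one, gave as many genes (5408, the highest other 4354). A chance split of these libraries is thus an unlikely source of that count. The splits treat the libraries as independent, which the labels do not state, so chance differences between cultures or harvests cannot be excluded.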

How the results depend on the processing

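Library totals alone were chosen after seeing the data; all other alternatives were planned. Over all alternatives, 412 values of the main counts lay within 1.5 times, 9 were higher, 26 lower and 0 reversed. For named genes 10835 values kept their side of the threshold, 50 gained a call, 131 lost one and 4 reversed in sign. For lists these were 1875, 108, 122 and 1. In the order C0 against BY47419, C3-06, C5-63 and C7-143 against C0, C5-63 against C3-06 and C7-143 against C5-63, an estimated correlation called 0, 0, 0, 0, 0 and 0 lists, and fry 21, 35, 37, 38, 24 and 27; fry does not compare a list with other genes. At an adjusted p below 0.01, by construction stricter, C0 against BY47419 had 300 genes higher and 513 lower, C5-63 against C3-06 703 and 801, and C7-143 against C5-63 884 lower. With only the strains compared in the fit (fewer samples), C0 against BY47419 had 566 genes lower, 21 of them at least 2-fold. Library totals gave 1279 higher and 318 lower in C0 against BY47419 (75 at least 2-fold higher), 761 lower in C5-63 against C3-06, and 714 higher and 2314 lower in C7-143 against C5-63 (52 and 99 at least 2-fold). They also reversed the sign of ERG8 against C0 in C3-06 (0.17) and C5-63 (0.30), and of HMG2 (0.059) and IDI1 (0.26) in C5-63; the phosphate list in C7-143 against C0 reversed under fry (adjusted p = 0.000193). The cause was not tested for these reversals. Leaving out 1 library gave 377 (without BY47419 replicate 1) to 976 (without BY47419 replicate 2) genes higher and 568 to 1247 lower in C0 against BY47419, also 389 and 625 without BY47419 replicate 3 and 392 and 635 without C0 replicate 2. It gave 67 (without C3-06 replicate 1) to 158 (without C3-06 replicate 2) at least 2-fold lower in C5-63 against C3-06, and 35 (without C7-143 replicate 2) to 69 (without C7-143 replicate 3), with 37 without C5-63 replicate 2, in C7-143 against C5-63. Only C0 against BY47419 passed the limit for pairing by replicate number, which can also happen by chance. There the block ended the calls of the oxidative stress list (camera, 0.0666) and PAU2 (edgeR, 0.0593) and gave ERG7 one (edgeR, 0.0304). It took the PAU count from 5 to 3 of 16 and changed no other call of a list or named gene. The other comparisons did not pass the limit: over all strains same-numbered samples correlated at -0.43 to 0.33 in 30 pairs, 10 above 0.1, and 6 of 15 samples correlated best with their own number. With the replicate block the genes higher and lower were 725 and 1057, 2393 and 2300, 2406 and 2411, 2485 and 2519, 1176 and 1238, and 1463 and 1391 in the order above, the joint count was 5406 and the lists called 12, 16, 16, 20, 17 and 21, with none of these counts moved by over 1.5 times. Depth limits the genes at 0 reads, whose folds are lower bounds.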

Other observations

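The additional gene lists, the test of neighbouring genes without GAL3 and GAL80 and the p without the SUR7 pair were chosen only after the results were seen; the test of neighbouring genes itself was written before, when the adjacency of SUR7 and GAL80 was already known.

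Genes for DNA replication, translation and glycosylation also rose in C7-143 against C0, in lists put together after the data had been examined. RNR1, the large subunit of ribonucleotide reductase, rose from 7.47 ± 1.21 to 210.1 ± 32.3 CPM (SD, n = 3), a log2 fold change of 4.81 ± 0.23 (SE; adjusted p = 1.35e-11, edgeR), and the replication factor CDC45 by 3.07 ± 0.14. DNA replication genes rose in 25 of 27 members (median 1.28), with MCM3 (0.19) and MCM4 (0.05) not passing. Cytosolic aminoacyl-tRNA synthetase genes rose in 17 of 19 with 1 the other way (median 2.42), translation factor genes in 23 of 26 with 1 the other way (1.61), purine synthesis genes in 16 of 20 with 3 the other way (1.58) and protein glycosylation genes in 30 of 32 with 2 the other way (1.59). Autophagy genes fell in 28 of 34 with 4 the other way (-1.28). Camera called these 6 lists at its preset correlation, and each was at adjusted p = 0.176 with an estimated correlation. Genes of mitochondrial ribosomal proteins fell in 38 of 54 with 3 the other way (-0.42), and MRPL28 fell by 1.77 (SE 0.08; adjusted p = 0.291 for the list with an estimated correlation). Histone genes, with 6 of 10 higher and 2 lower, were not called (adjusted p = 0.175, and 0.612 with an estimated correlation).

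SUR7, a plasma membrane protein gene next to GAL80 on chromosome XIII, went from 104 CPM in BY47419 to 885 in C0, and stood at 510, 253 and 192 CPM in C3-06, C5-63 and C7-143. It was singled out after its values were seen. Of the 93 genes changed at least 2-fold between C0 and BY47419, the 3 of the adjacent GAL1, GAL10 and GAL7 cluster were left out, and the other 90 formed 4 adjacent pairs where permuted gene positions gave a mean of 1.36 (permutation p = 0.0458, 10000 permutations): GAL3 with YDR010C, SUR7 with GAL80, AAD15 with YOL164W-A, and YPL067C with RGL1. The SUR7 pair was known before, and with it not counted the permutation p was 0.157. Without GAL3 and GAL80 there were 2 pairs against 1.32 (permutation p = 0.384). Whether neighbouring genes changed together more often than by chance stays open, and the strand setting of the counts, which is not given in the sources used here, leaves the GAL3 pair uncertain.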
